A study of Saccharum officinarum x Saccharum spontaneum with 21 samples.

How the data were processed

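The series comprised 21 RNA-seq libraries from leaves of the sugarcane hybrid ZZ1 inoculated with Fusarium sacchari, 3 at each of 7 times. Per the labels' protocols, plants were kept in a greenhouse with 14 h of light and 10 h of darkness a day, messenger RNA was selected with poly-T beads, and libraries were made with the NEBNext Ultra RNA kit and sequenced on an Illumina NovaSeq instrument. The values used were the counts per gene ID that the authors deposited as a single table with 1 column per library. Per the submitters' processing notes, the tools were fastp 0.20.0, HISAT2 2.1.0, featureCounts, Subread 1.6.2 and DESeq2 1.22.1, with no role or order stated. The genome build, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited counts were whole numbers with different totals per library, as unnormalised counts are. A value of 1 occurred 62076 times and a value of 2 occurred 97150 times, so a unit of the table may not be a single read or fragment, and statements on counting error carry that limit.

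Of the 149266 IDs, 83821 started with Sspon. and 65445 with NewGene_. No table pairing these IDs with gene names, descriptions or coordinates was used here. The gene lists fixed beforehand (defence, hormone, cell wall, photosynthesis, clock and others) were to be matched to names, so their tests were not run. Under the rule fixed for that case, the IDs to be named were the 2 that rose and the 2 that fell with the largest mean log2 fold change over the 6 comparisons with 0 h, among those called in the same direction at all 6 times with a mean of at least 5 CPM in the higher groups. Without strand information, reads of overlapping genes cannot be told apart, and near-identical copies, which a polyploid hybrid holds, can share reads. The part of an Sspon. ID before the hyphen is called its stem; what the stem stands for is not given in the sources used here.

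Samples were grouped by the time after inoculation in the labels, and columns were matched to samples by library name. To look for a library deposited more than once, replicates of a time were compared by a chi-square test of their counts. No pair agreed within sampling noise (chi-square per degree of freedom of at least 15.3), so none were merged; this does not show that they came from different plants, for which the labels are the source. Counts were analysed in R 4.3.3 with edgeR 4.0.16. IDs were kept by filterByExpr with its default minimum count of 10 and minimum total count of 15, which left 106585 IDs (71.4%). Library sizes were scaled by TMM factors, which ranged from 0.85 to 1.213. A model of 7 group means was fitted to all 21 libraries with glmQLFit, and each of 8 contrasts (the 6 later times against 0 h, 24 h against 12 h and 144 h against 24 h) was tested with glmQLFTest, along with an F test of any difference among the 7 times. IDs with a Benjamini-Hochberg adjusted p under 0.05 were called, with no fold minimum. These groups, contrasts, tests and most alternatives were fixed before the data were examined.

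Standard errors of log2 fold changes were obtained from the fold change and its F statistic. CPM values used the TMM-scaled library sizes, and principal components and distances used log2 CPM with a prior count of 2. Where a group had 0 counts in every library, a fold is given only as a bound against a floor of 3 counts over the group, and medians of log2 fold changes are given also with such IDs at that bound. Floors cover counting error only. The floor of 3 counts in a single library was between 0.0992 and 0.151 CPM. IDs called at 12 h and called the opposite way between 12 h and 24 h are described as returned, whether or not they were still called against 0 h at 24 h. Overlaps between comparisons that share the 0 h libraries were set beside 5 simulations of unchanged groups and beside the overlap of independent lists.

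The test was checked on simulated data for 144 h against 0 h, with counts drawn for the 106585 IDs and 200 of them changed. It recovered 0% of the IDs changed by 2-fold, 1.49% of those changed by 4-fold and 42.4% of those changed by 8-fold, and called 1 unchanged ID. These rates hold for that simulation only, since with few changed IDs the adjusted threshold is stricter than with the 18010 calls of the real comparison, whose smallest absolute log2 fold change was 0.58. An ID that was not called is not shown to be unchanged.

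Alternatives were size factors by the median of ratios (RLE), scaling by total counts alone, no filter, a filter of at least 1 CPM in 3 libraries, an adjusted p under 0.01, a minimum absolute log2 fold change of 1, fits of only the groups compared, the replicate number as a block, DESeq2 1.42.0 on the same IDs, a prior count of 5, and each library left out in turn. An alternative with counts summed over the IDs of a stem was added after seeing the data.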

Results

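Gene expression was measured by RNA sequencing of poly-A RNA in leaves of ZZ1, a hybrid of the sugarcane species Saccharum officinarum and Saccharum spontaneum. The leaves had been inoculated with spores of Fusarium sacchari, a fungal pathogen of sugarcane. Leaves were collected at 0 h, which served as the control, and at 12, 24, 48, 72, 120 and 144 h after inoculation. Each of the 7 times had 3 libraries, described by the labels as biological replicates, which gave 21 libraries. A mock-inoculated time course was not analysed here, so each comparison with 0 h contains the effect of inoculation together with those of handling and leaf age. The comparison at 12 h, the only time not a whole number of days after 0 h, also contains that of time of day. The deposited table held counts for 149266 gene IDs, of which 106585 had enough counts to be tested. Total counts ranged from 19830238 in 72 h replicate 3 to 30247449 in 0 h replicate 3. The number of IDs with at least 1 count ranged from 104311 in 72 h replicate 3 to 120355 in 48 h replicate 1. The table did not pair its IDs with gene names, so genes are described by their behaviour over time, and only 4 IDs, chosen by a fixed rule, are given by name.

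The first question was how the leaf transcriptome as a whole was ordered over the infection. Libraries were ordered along the first principal component mainly by time. This component held 27.2% of the variance of log2 CPM (counts scaled to library size), and its mean score was -284.8 ± 31 at 0 h, -168.3 ± 140.2 at 12 h, 13 ± 85 at 24 h, 12.1 ± 68.7 at 48 h, 98.1 ± 38.2 at 72 h, 97.9 ± 69.8 at 120 h and 232.1 ± 33.1 at 144 h (SD, n = 3 each). The 0 h and 144 h groups had the lowest and the highest mean, the groups between them overlapped, and the lowest single score was that of 12 h replicate 1 (-323). The mean distance between libraries of the same time was 1.267 on the log2 scale, against 1.467 between libraries of different times. The nearest library belonged to the same time for 9 of the 21 libraries. Replicate 1 at 12 h lay nearest to 0 h replicate 2, and 72 h replicate 3 stood apart on the second component, with a score of -419.3.

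**Figure D1:**
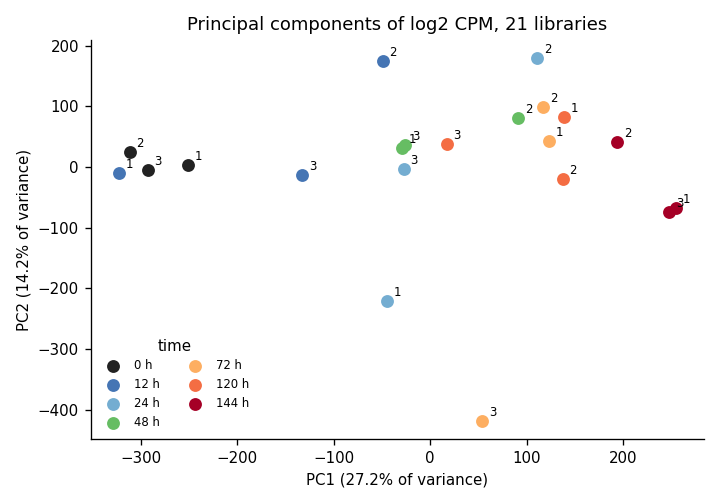
Scores of the 21 libraries on the first and second principal components of log2 CPM (log2 units); each point is a library, coloured by hours after inoculation and numbered by replicate. The 0 h libraries lie at the left and the 144 h libraries at the right, with 12 h replicate 1 among the 0 h libraries and 72 h replicate 3 alone at the bottom.

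Expression of 10573 IDs, or 9.92% of those tested, differed among the 7 times in edgeR's quasi-likelihood F test at a Benjamini-Hochberg adjusted p under 0.05. Among these IDs the largest change from 0 h fell at 144 h for 62% and at 72 h for 19.2%, and at each of the other times for between 3.6% and 5.84%. The count was 6223 without 0 h replicate 2, 6823 without 144 h replicate 1 and 6849 without 144 h replicate 3. DESeq2 called 23725 IDs.

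The comparison of each time with 0 h asked when after inoculation genes rose or fell. At 12 h, 352 IDs were higher and 321 lower than at 0 h, 0.631% of those tested. The median fitted log2 fold change was 4.29 for the higher IDs, or 4.14 with the 48 IDs absent from a whole group set to the bound that 3 counts over the group allow, and -2.85 for the lower IDs on either scale. This was the smallest set of changes against 0 h. More IDs were lower than higher with scaling by total counts alone (294 higher, 366 lower), with only the 12 h and 0 h libraries fitted (21 and 48), without any single 0 h library (99 and 170, 80 and 189, and 129 and 230 for replicates 1, 2 and 3), without 12 h replicate 3 (137 and 174) and at an adjusted p under 0.01 (78 and 144). The higher share rose without 12 h replicate 1 (1734 higher, 362 lower) and in DESeq2 (2571 and 1092). The total of 673 was 269, 269 and 359 without 0 h replicates 1, 2 and 3. It was 2096, 413 and 311 without 12 h replicates 1, 2 and 3, and DESeq2 called 3663.

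More IDs were called against 0 h at 24 h than at 12 h, and more of the 24 h IDs were higher than lower. How much larger the 24 h count was depended on single libraries. Without 12 h replicate 1, 2096 IDs were called at 12 h, and without 24 h replicate 2, 1972 were called at 24 h. With all libraries, 2631 IDs were higher and 1222 lower at 24 h than at 0 h. Their median log2 fold changes were 3.37 (3.27 with absent groups at their bound) and -2.2. At 48 h, 1979 IDs were higher and 1108 lower, with medians of 3.9 (3.63 at the bound) and -2.24. Of the higher IDs, 78.9% at 24 h and 83.3% at 48 h differed by at least 4-fold, against 58.1% and 62.1% of the lower IDs. These shares cover called IDs only, and the test recovered small changes poorly in the simulated data. A group at 0 counts was involved for 390 and 364 of the higher IDs, against 31 and 23 of the lower IDs. The shares therefore do not show that rises were larger than falls among all IDs. Scaling by total counts moved the higher share at 48 h from 64.1% to 78.4%, and with it the median log2 fold change of all tested IDs from 0.09 to 0.26. The higher share also moved with single libraries. At 24 h it was 68.3% with all libraries, 54.5% without 0 h replicate 3 and 77% without 24 h replicate 2. At 48 h it was 52.5% without 0 h replicate 3 and 80.7% without 48 h replicate 1. With only the 48 h and 0 h libraries fitted, 2362 IDs were higher and 2181 lower. The 3853 calls at 24 h became 1442, 644 and 1610 without 0 h replicates 1, 2 and 3, 1972 and 2357 without 24 h replicates 2 and 3, 1194 with only both groups fitted and 10219 in DESeq2. The 3087 calls at 48 h became 884, 458 and 1102 without 0 h replicates 1, 2 and 3, 1919 and 566 without 48 h replicates 1 and 2, and 9530 in DESeq2.

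At 72 h, 6265 IDs were higher and 4220 lower than at 0 h, and at 120 h 4321 were higher and 2132 lower. The median log2 fold change of the higher IDs was 3.2 at 72 h (3.17 at the bound) and 3.86 at 120 h (3.69 at the bound), and that of the lower IDs was -2.24 and -2.04. The higher share was 59.8% at 72 h, 51.6% without 0 h replicate 3 and 68.1% without 72 h replicate 1. At 120 h it was 67%, 62.3% without 0 h replicate 3 and 85% without 120 h replicate 1. Whether the response at 120 h differed from that at 72 h was not tested directly. The 10485 calls at 72 h became 5693 and 4105 without 0 h replicates 1 and 2, 6485 without 72 h replicate 1, 5902 with only both groups fitted and 18003 in DESeq2. The 6453 calls at 120 h became 3029, 1922 and 2923 without 0 h replicates 1, 2 and 3, 2714 and 3541 without 120 h replicates 1 and 2, and 13861 in DESeq2.

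The change was broadest at 144 h, the last time collected. Here 10077 IDs were higher and 7933 lower than at 0 h, together 16.9% of those tested. Median log2 fold changes were 3.15 for the higher IDs (3.13 at the bound) and -2.26 for the lower IDs, and 71.5% and 60.6% of them differed by at least 4-fold. These shares again cover called IDs only, of which 1218 higher and 277 lower had a group at 0 counts. With scaling by total counts, 8937 IDs were higher and 9059 lower, and the median log2 fold change of all tested IDs moved from 0.02 to -0.11, so that which direction held more IDs depended on the scaling. The higher share of 56% was 50.8% without 0 h replicate 3 and 62.1% without 144 h replicate 3. The 18010 calls became 10547 without 0 h replicate 2, and 10711 and 10896 without 144 h replicates 1 and 3.

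**Figure D2:**
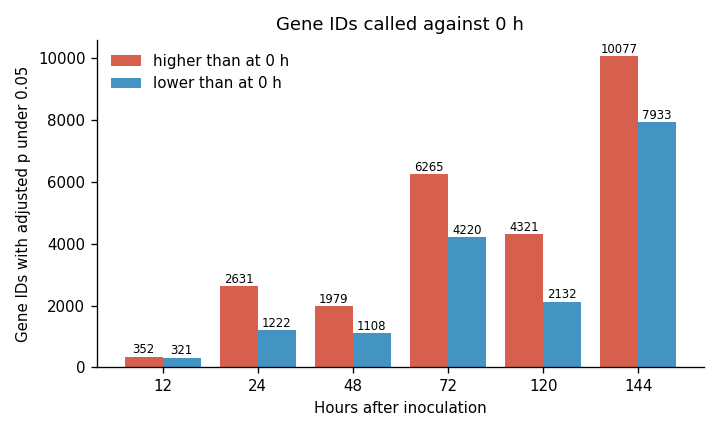
Number of gene IDs higher or lower than at 0 h at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, by hours after inoculation (3 libraries per time); each bar is a count over the 106585 IDs tested and carries no error bar. Counts run from 352 higher and 321 lower at 12 h to 10077 higher and 7933 lower at 144 h.

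A group of IDs appeared in every library of a later time where the control showed none. At 144 h, 546 IDs had at least 20 counts in each of the 3 libraries and 0 counts in every 0 h library. The corresponding numbers were 12 at 12 h, 130 at 24 h, 167 at 48 h, 208 at 72 h and 281 at 120 h. The opposite pattern, at least 20 counts in each 0 h library and 0 in each later one, held for 17, 23, 22, 55, 27 and 90 IDs at 12, 24, 48, 72, 120 and 144 h. The highest number in any other split of the same 6 libraries was 10 at 12 h, 28 at 24 h, 11 at 48 h, 25 at 72 h, 28 at 120 h and 11 at 144 h, so both 12 h numbers were close to those of other splits, and the losses at 24 h and 120 h did not exceed them.

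Whether the same genes changed throughout the series was asked from the overlap of the calls. In all, 21015 IDs were called at 1 or more of the 6 later times, and 11 of them were higher at one time and lower at another. Expression was higher at all 6 times for 214 IDs and lower at all 6 for 79. The median fitted log2 fold change of the 214 IDs was 5.23 at 12 h, 6.1 at 24 h and 7.14 at 144 h, or 4.71, 5.65 and 6.44 with the 45 IDs absent at 0 h set to their bound. That of the 79 IDs was -3.17, -2.71 and -2.72. Independent lists of the same sizes would share 3.63e-05 higher and 2.26e-06 lower IDs, and 5 simulations of unchanged groups against the same controls gave 0, having given no call by edgeR's test in any comparison; with 3 controls, which cannot be split, part of the excess may come from the shared controls. The total of 293 was 77, 63 and 111 without 0 h replicates 1, 2 and 3 (48 higher and 29 lower, 32 and 31, and 59 and 52), so that the surplus of higher IDs was small without replicate 2 or 3, as it was at an adjusted p under 0.01 (25 and 23). It was 1099, 179 and 117 without 12 h replicates 1, 2 and 3 (1007 and 92, 121 and 58, and 66 and 51), 159 without 48 h replicate 2, 180 without 120 h replicate 1, 14 (2 higher, 12 lower) with only both groups fitted in each comparison and 1690 in DESeq2.

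Most IDs called at an earlier time were also called in the same direction at 144 h. This held for 94.3% of the higher and 82.9% of the lower IDs of 24 h, for 95.1% and 84.5% of those of 48 h, for 81.3% and 74.2% of those of 72 h, and for 93.8% and 89.3% of those of 120 h. At 12 h the shares were 75.9% and 53%. For 24 h these shares were 2480 higher and 1013 lower IDs, against 249 and 91 for independent lists, but the same 0 h libraries entered both sides, so these are not the values that shared controls give with no change. The simulations of unchanged groups gave no calls and so no such value.

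The rule for named IDs took those called in the same direction at all 6 times with the largest mean change. Sspon.03G0019550-2B and Sspon.03G0019550-1P rose. Neither had a count in the 0 h libraries, and at 144 h they stood at 130 ± 30.8 and 125 ± 30.8 CPM (SD, n = 3). These levels were at least 3670-fold and 3510-fold higher than the level that 3 counts over the 0 h group would give. At 12 h they stood at 32 ± 40.6 and 24.2 ± 32.7 CPM (SD, n = 3), with 14 and 0 counts in replicate 1 against 1853 and 1462 in replicate 3. Their fitted log2 fold changes at 144 h were 14.66 (SE 2.02, adjusted p = 0.00047) and 14.6 (SE 2.39, adjusted p = 0.0011) in edgeR's quasi-likelihood test. These fold changes, and the SEs obtained from them, depend on the prior count because the control is 0. Both IDs have the same part before the hyphen and similar counts at 144 h (8091 and 7753 over the group; 2297 and 1737 at 12 h), so their reads may be shared and their separate levels are uncertain. Without any single 0 h library, or without 12 h replicate 3, Sspon.03G0019550-1P was called at 4 or 5 of the 6 times, with mean log2 fold changes from 12.89 to 13.24, and with only both groups fitted each of the pair was called at 5.

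Sspon.02G0003080-2C and NewGene_60681 fell. Sspon.02G0003080-2C went from 55.6 ± 7.48 CPM at 0 h to 0.0563 ± 0.0975 CPM at 144 h (SD, n = 3), a log2 fold change of -9.68 (SE 1.33, adjusted p = 0.00047 in edgeR's quasi-likelihood test). It had 0 counts in all 48 h libraries, at least 1470-fold lower than at 0 h by the floor of 3 counts over the group. NewGene_60681 went from 90.3 ± 16.8 CPM at 0 h to 0.143 ± 0.132 CPM at 144 h (SD, n = 3), a log2 fold change of -9.24 (SE 1.72, adjusted p = 0.0019 in the same edgeR test). Its smallest change was at 120 h, where it stood at 2.32 ± 1.86 CPM (SD, n = 3) with a log2 fold change of -5.28 (SE 1.38, adjusted p = 0.032 in edgeR). In 12 h replicate 1 these IDs had 0 and 10 counts, against at least 1443 and 2250 in each 0 h library. NewGene_60681 was called at 4 of the 6 times without 0 h replicate 2, and at 5 without 0 h replicate 1 or 3, 12 h replicate 2 or 3, 24 h replicate 3, 48 h replicate 2 or any single 120 h library, with mean log2 fold changes from -7.95 to -7.69, and at 5 with only both groups fitted.

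**Figure D3:**
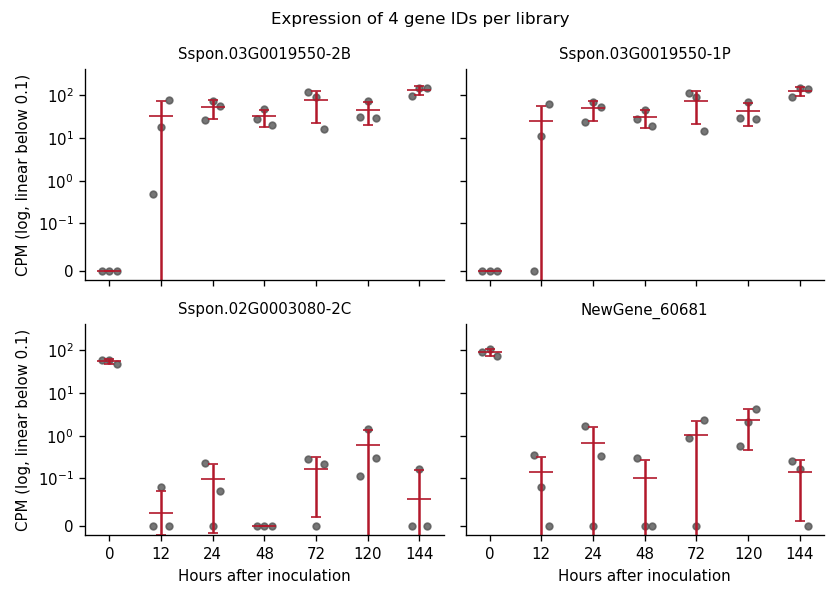
CPM (log axis, linear below 0.1) of the 4 named IDs by hours after inoculation; grey points are libraries, red marks are means of 3 libraries and bars are SD. The upper panels go from 0 counts at 0 h to 130 and 125 CPM at 144 h, and the lower panels from 55.6 and 90.3 CPM at 0 h to under 0.15 CPM at 144 h.

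The comparison of 24 h with 12 h asked which early changes had reversed by 24 h. Between these times 89 IDs were higher at 24 h and 127 lower. Another grouping of the same libraries, with 24 h replicates 1 and 3 and 12 h replicate 1 against the rest, gave 1416 calls against 216. Of the 673 IDs called at 12 h, 68 (10.1%) were called in the opposite direction between 12 h and 24 h, namely 38 of the 352 higher and 30 of the 321 lower IDs. The median log2 fold change against 0 h of the 38 IDs was 4.31 at 12 h, 0.11 at 24 h and 0.18 at 144 h, and that of the 30 IDs was -3.85, -0.47 and -0.28. The direction of the change from 12 h to 24 h follows from how these IDs were chosen, while the 144 h libraries took no part in that choice. For some the reversal was partial, since 6 of the 38 and 7 of the 30 were still called in their 12 h direction against 0 h at 24 h, and 11 and 9 were called in that direction at 1 or more of the times from 48 to 144 h. With scaling by total counts the split between 24 h and 12 h turned to 120 higher and 81 lower, the returning IDs to 28 higher and 44 lower at 12 h, and the median log2 fold change of all tested IDs from 0 to 0.15. The split also turned without 12 h replicate 1 (23 higher, 21 lower), 12 h replicate 3 (254 and 148), 24 h replicate 1 (38 and 27) and 24 h replicate 2 (65 and 32), and the total was 67 without 24 h replicate 3. With only the 12 h and 24 h libraries fitted, edgeR called 0 IDs between 12 h and 24 h, with 6424 at an unadjusted p under 0.05, and therefore 0 returning IDs; DESeq2 called 2611 between these times and 356 returning. The 68 returning IDs became 39 without 0 h replicate 2, 31 without 12 h replicate 1, and 28, 44 and 30 without 24 h replicates 1, 2 and 3.

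**Figure D4:**
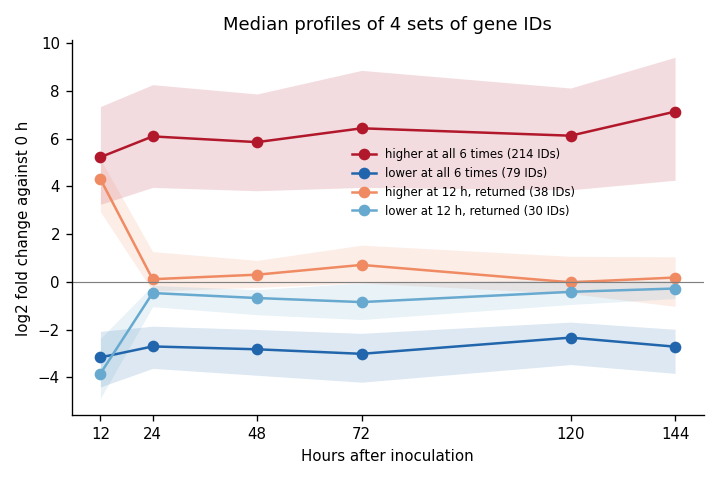
Median log2 fold change against 0 h (lines) with the quartiles over IDs (shading) by hours after inoculation, for IDs higher or lower at all 6 times and for IDs that were higher or lower at 12 h and returned by 24 h. The 214 sustained higher IDs lie between 5.23 and 7.14 (fitted values, which for IDs absent at 0 h are no bound), while the 38 higher IDs that returned go from 4.31 at 12 h to 0.11 at 24 h, a direction fixed by their choice.

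The comparison of 144 h with 24 h asked how the late response differed from the early one. At 144 h, 378 IDs were higher and 81 lower than at 24 h, with median log2 fold changes of 3.94 and -2.59 (-2.55 at the bound). The total of 459 was 80 and 18 without 24 h replicates 1 and 3, and 102 and 89 without 144 h replicates 1 and 3. Without 24 h replicate 2 it was 624, and the direction turned, with 239 higher and 385 lower. DESeq2 called 3483, and scaling by total counts moved the median log2 fold change of all tested IDs from -0.08 to -0.23.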

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

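The summed counts per stem were chosen after the data were seen; the other settings were planned. Against the main counts, 78 of 109 counts under other settings and 47 of 99 with a library left out lay within 1.5 times. The cause of the differences was not tested, except that a stricter threshold calls fewer IDs and summed stems leave fewer units to test. A left-out library leaves fewer samples, but some counts rose. The calls at 12 h went from 673 to 2096 without 12 h replicate 1. Those between 24 h and 12 h went from 216 to 402 without 12 h replicate 3. The smaller number of samples alone therefore cannot be taken as the cause. At an adjusted p under 0.01 the calls against 0 h were 222, 664, 413, 3143, 1599 and 7882 at 12, 24, 48, 72, 120 and 144 h, with 34 between 24 h and 12 h, 21 between 144 h and 24 h, 4303 for any difference, 48 at all 6 times and 22 returning. DESeq2 gave 3663, 10219, 9530, 18003 and 13861 calls at 12 to 120 h, 2611 between 24 h and 12 h, 3483 between 144 h and 24 h, 23725 for any difference, 1690 at all 6 times and 356 returning; its 25112 at 144 h lay within the limit. With only the groups compared in the fit, the calls were 69 at 12 h, 1194 at 24 h and 5902 at 72 h, with 14 at all 6 times. In these fits edgeR called 0 between 24 h and 12 h (6424 at an unadjusted p under 0.05) and 0 returning. At the other times they gave more calls than the main fit, though within the limit. These were 4543 against 3087 at 48 h, 9003 against 6453 at 120 h and 25767 against 18010 at 144 h. Summed stems, with 70091 units tested, gave 427 at 12 h, 11896 at 144 h, 136 between 24 h and 12 h and 39 returning. With a library left out, the ranges were 269 to 2096 at 12 h, 644 to 3299 at 24 h, 458 to 2340 at 48 h, 4105 to 8430 at 72 h, 1922 to 5134 at 120 h, 10547 to 14877 at 144 h, 44 to 402 between 24 h and 12 h, 18 to 624 between 144 h and 24 h, 6223 to 12380 for any difference, 63 to 1099 at all 6 times and 28 to 68 returning. The 4 named IDs had the same sign in all 121 values and missed a call at 1 or more of the 6 times in 20 of them, down to 2 times for NewGene_60681 at an adjusted p under 0.01. The replicate numbers did not clearly pair the samples: 22 of 63 same-number pairs correlated over 0.1, and 8 of 21 libraries correlated best with their own number. The median correlation was 0.03 for the same number and -0.02 for different numbers, with a highest same-number value of 0.48. A factor shared by some libraries of a number was not excluded, as the library nearest to 12 h replicate 2 was 24 h replicate 2. The replicate block gave 571, 3343, 2711, 10334, 6206 and 18597 calls at 12 to 144 h, 160 between 24 h and 12 h, 396 between 144 h and 24 h, 9675 for any difference, 222 at all 6 times and 58 returning, all within 1.5 times, with 253 higher and 318 lower at 12 h and Sspon.03G0019550-1P called at 5 times. Depth limits IDs with low counts most: 3 counts in a library were worth 0.0992 to 0.151 CPM. The planned tests of gene lists were not run, as no names were matched.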

Other observations

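The tests of time of day, of reads moving within a stem and of a wrong label or a mix for 12 h replicate 1 were chosen or revised only after the results were seen, and that of chance 12 h values replaced a first version whose outcome was fixed at 0. IDs of the same stem changed together. Among the tested IDs, 17479 stems had at least 2 IDs, which made 69306 pairs. Both IDs were called at 144 h against 0 h in 9501 pairs, and in 99% of these they changed in the same direction, against 50.5% of shuffled pairs. Across pairs, which are not independent replicates, Pearson's r of the log2 fold changes at 144 h was 0.8, against 0 for shuffled pairs. When an ID was called, the other ID of its stem was called in the same direction in 65.6% of cases and in the opposite direction in 0.677%. Summing counts over stems gave 11896 calls among 70091 units tested at 144 h, in place of 18010 among 106585 IDs. The number of IDs thus overstates the number of independent units that changed, but the units tested fell as well. Reads shared between the IDs of a stem may contribute to the concordance. IDs starting with NewGene_ made up 32.9% of the calls at 144 h, while 45007 of the 106585 tested IDs started so, and the difference was not tested.

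The 68 IDs that changed at 12 h and returned by 24 h are of interest because 12 h was the only time that was not a whole number of days after 0 h. If time of day had set them, little of the 12 h change should be left at 48 to 144 h, and the median share left was 0.12 (quartiles -0.04 and 0.27). A brief response to inoculation would leave the same values, so these explanations stay open, with no mock series analysed here to separate them. Chance values of the shared 12 h libraries were tested by choosing returning IDs without 1 of these libraries and reading them in it, against the 48 to 144 h mean. The library kept out showed a median of 1.06, 0.77 and 0.83 of the 12 h change of the other two for replicates 1, 2 and 3 (31, 64 and 68 IDs). The lowest, 0.77, lies above 0 by more than 0.16, the SD of these 3 medians, which come from fits that share libraries. This argues against chance values of single 12 h libraries as the source. Chance values of the 24 h libraries, which also define a return, were not tested. Not all of the 68 went back fully, with 6 higher and 7 lower IDs still called against 0 h at 24 h, and the set was 31 without 12 h replicate 1 and 28 without 24 h replicate 1.

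Replicate 1 at 12 h lay closer to the 0 h libraries (mean distance 1.16) than to the other 12 h libraries (1.479), and without it the calls at 12 h went from 673 to 2096. A 0 h library with the wrong label was tested by the median share of the 24 to 144 h change it showed; a first version, 0.14 against at most 0 for the 0 h libraries, was replaced because those libraries had helped to choose the IDs, which holds their shares near 0. With each 0 h library in turn kept out of the choice and the baseline, the kept-out 0 h libraries showed 0.15, 0 and 0.14, and 12 h replicate 1 showed 0.27, 0.3 and 0.27 on the same IDs. Its lowest value, 0.27, passed the bound of 0.23 (the highest 0 h value plus the SD of the 3), a narrow margin from 3 reference libraries. On the 31 returning IDs chosen without it, this library showed 1.06 of the 12 h change (quartiles 0.87 and 1.14), which also argues against a 0 h library. A mix of other 12 h material with a 0 h library is argued against too: with 0 h replicate 1, 2 or 3 kept out of the choice of IDs, the mix that matched its 0.27, 0.3 or 0.27 held 91%, 67% or 90% of 0 h material. On the returning IDs chosen without both libraries, these mixes gave 0.47, 0.76 and 0.48 of the 12 h change for the 8, 5 and 8 higher IDs (lower quartiles observed 1.11, 1.12 and 1.13), and -0.08, -0.01 and -0.07 for the 15, 14 and 15 lower IDs (lower quartiles 0.29, 0.5 and 0.29); a weaker or later response in those leaves stays open and untested.

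Many IDs were at or near 0 counts in 1 library of a time and well above 0 in both others. In 2822 cases, over 2238 IDs, an ID had 0 counts in 1 library and at least 50 in both others of its time, and 827 of these cases were in 72 h replicate 3. Counting noise with the fitted spread gave at most 657 such cases in 5 simulated draws, which argues against noise with that spread for the cases at 0. The draws used a single spread per ID for all times. The largest distance within a time was 1.851 at 72 h and 1.131 at 0 h. A larger spread at some times was therefore not covered by the draws and stays open. With 1 to 5 counts in place of 0 there were 3003 cases, against at most 2304 in the draws. Near-0 cases were thus at least as frequent as cases at 0, with a smaller excess over the draws. The stem counts that follow cover the cases at 0. In the 1747 cases with another tested ID of the stem, reads moving to those IDs are argued against as the general cause by their median change of -1.04 in units of the CPM lost (quartiles -2.77 and -0.15), though in 11.7% they gained at least 0.5 of the loss; for the other 1075 cases no such ID was tested and this cannot be told apart. Lower depth of 72 h replicate 3 is argued against because, after all libraries were thinned to the same total, it still had 260 IDs at 1 count or less against at least 100 in both others, where the highest other library had 136. Differences between plants, and reads moving to IDs outside the stem, may account for such cases and were not tested.

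A wrong label for 72 h replicate 3, whose nearest library was 24 h replicate 1, was also examined. This test was undecided and was dropped from the planned list after its result was seen. The mean Spearman correlation of 72 h replicate 3 with the other libraries was 0.78 for its own time, and 0.784 for 24 h and for 144 h, with an SD over libraries of 0.037. Values this close cannot tell its time, so its label stays unsettled by them.

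Other splits of the libraries were counted for each comparison. The 10 splits of 3 against 3 are too few for a share under 0.05. For the comparisons with 0 h the real counts were 673, 3853, 3087, 10485, 6453 and 18010, and the highest other split gave 1, 1, 0, 2, 1 and 1 calls by edgeR's test; for 144 h against 24 h they were 459 and 1. For 24 h against 12 h another split, with 24 h replicates 1 and 3 and 12 h replicate 1 against the rest, gave 1416 calls against 216, so that 2 of the 10 splits gave at least the real count. Such a number points to a structure of the samples other than their time. On the second principal component, 12 h replicate 2 and 24 h replicate 2 scored 174.7 and 178.9, and 24 h replicate 1 scored -220.2. The other libraries of these times lay between -12.8 and -2.9. For any difference among the 7 times, 1 of 25 groupings, the real one, gave as many as 10573 calls, and the highest other gave 174. This share is under 0.05, which argues against chance there, but it is the smallest share that 25 groupings can give.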
